A study of Mus musculus with 8 samples.

How the data were processed

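White quadriceps RNA in 8 samples from male mice was sequenced, 4 with loxP-flanked Acot2 and no Cre (control) and 4 with Cre (knockout), after 7 days on a 60% fat diet. Per the labels' protocols, total RNA was extracted with a Norgen Biotek kit and libraries were made with a NEBNext Ultra II kit for Illumina. Per the submitters' processing notes, cutadapt, FastQC, STAR, HTSeq and DESeq2 were used with the genome build GRCm38. Their versions, their settings, the gene annotation, the strand setting and how ribosomal RNA was removed are not given in the sources used here.

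The deposited values are on a log2 scale. Their form is inferred from the numbers: with the log2 undone and 1 subtracted, each sample's deposited values are whole multiples of 1 step per sample (0.679 to 1.29), as whole reads per gene divided by a size factor per sample would be. Of the values between 1 and 1000 reads, 100% lay within 0.1 of a whole read in every sample. Values are not divided by gene length. The table has 54091 rows, of which 27189 are above 0 in any sample, and 27 gene names that a spreadsheet had turned into dates were restored through their Entrez identifiers. The recovered depth was 55283997 to 109101280 reads per library, so that 3 reads, the floor taken for a gene not detected, correspond to a normalized count of 2.04 to 3.87. These figures cover counting error only.

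Groups and replicate numbers came from the labels, and all sample columns were used. Replicates of a group were checked against each other: over the 12 pairs within groups, the chi-square per gene of recovered reads was 35.4 to 265, far above the value near 1 of a library deposited repeatedly, and each counted as a sample of its own. Normalized counts are printed as mean ± SD over 4 libraries. Genes with a mean normalized count of at least 10 (15657) were tested with limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with the trend and robust options of eBayes and Benjamini-Hochberg adjustment at 0.05. Fold changes are on that scale, which understates the change of low genes. Differences are knockout minus control.

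Gene lists were fixed before the data were examined: 33 of pathways, complexes or responses and 12 of cell types. The 44 with at least 4 tested members were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists. An estimated correlation and fry were run beside it. Members of a list were also adjusted over the list alone. List scores are the mean deviation of the members from each gene's mean over the 8 libraries. Where a count test was foreseen only for raw counts, none was run, since the deposited unit is log2. limma voom was run on the recovered reads in its place.

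The named genes were set by a rule fixed in advance: the acyl-CoA thioesterases, the genes past the threshold with no overlap between groups (or the 5 of smallest p in a direction with fewer than 5 such genes), and the members of smallest p in each list. Genes outside it are said to be chosen after their values were seen, and 1 gene that the rule names is not reported here. Coordinates, exon lengths, GC content and overlaps between exons came from a GENCODE annotation of GRCm38, which need not be the one used for counting. The length and GC trend was removed from each library as a loess curve with a span of 0.5.

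The test was tried on simulated reads for these 8 libraries with 200 genes changed. It called 26.9% of genes changed by 1.5-fold, 56.7% at 2-fold and 89.4% at 4-fold, with 4 false calls among 119. Each gene was drawn independently, without the shared variation between genes of the real libraries, so the false calls need not carry over to them. The same folds were also put on genes of the real libraries, picked from those with a large unadjusted p between the groups. Of those tested, 31.7%, 56.1% and 87.3% were called, shares that hold for such genes only. Of 267 calls, 155 fell on other genes. All 155 had an unadjusted p under 0.05 before, and 1 had been called. Alternatives were other pseudocounts, filters, scalings and variance models, each replicate left out in turn, and other set tests. Those added after seeing the data were voom, the trend removal, and fits without control replicates 3 and 4 or without knockout replicates 6 and 8. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for tables and plots.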

Results

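Gene expression was measured by RNA sequencing in white quadriceps, the pale, mostly fast-twitch part of the thigh muscle, of male mice aged 11 to 14 weeks that had eaten a 60% fat diet for 7 days. The 4 control libraries (replicates 1 to 4) carried loxP sites at both copies of Acot2, and the 4 knockout libraries (replicates 5 to 8) came from mice that also carried a Cre recombinase, which deletes the DNA between loxP sites. Acot2 encodes a mitochondrial acyl-CoA thioesterase, an enzyme that splits long-chain acyl-CoA into free fatty acid and coenzyme A. The comparison asks which transcripts of glycolytic muscle differ without this enzyme when lipid supply is high. The labels name a knockout in muscle. Cre was present only in the knockout mice, so an effect of Cre itself cannot be told apart from that of losing Acot2. Reads recovered from the deposited values numbered 70286170, 70275633, 85095812 and 109101280 in control replicates 1 to 4, and 74996043, 55283997, 69655900 and 58359942 in knockout replicates 5 to 8. No source used here says that each library came from a separate animal, so p-values measure the spread between these samples.

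Acot2 was the only gene of 15657 tested that passed the threshold, and it fell to 10.6% of its control level. This count rests on single libraries and on the variance model: 1722 genes passed without control replicate 1, 2048 without control replicate 2 and 1201 with sample quality weights, and 1876 had an adjusted p under 0.1. Without control replicate 3, control replicate 4 or both, 1 gene passed. Control replicates 3 and 4 stood apart: on the first principal component (56.4% of the variance) they lay at 38 and 41.3. The other libraries lay between -27.8 and -1. The larger counts without control replicate 1 or 2 come from fits that keep both of these libraries, so they do not show a knockout response. Genes of fatty acid oxidation, fatty acid uptake, triglyceride handling, glycolysis and the TCA cycle did not shift as groups. Macrophage and fibro-adipogenic progenitor markers, ribosomal protein genes and nuclear genes of the respiratory chain rose as groups under a gene set test with a preset correlation, and the mRNAs encoded by mitochondrial DNA fell. None of these group calls held when the correlation between genes was estimated from the 8 libraries.

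Acot2 lies on the plus strand of chromosome 12 from 83987861 to 83993873 (GRCm38) and its annotated transcript has 3 exons. Its normalized count was 2179.1, 3347.7, 4165.4 and 2166.2 in control replicates 1 to 4, and 324.8, 273.4, 256.4 and 354 in knockout replicates 5 to 8. The group means were 2965 ± 974 and 302.2 ± 45.2 (SD, n = 4 each). The log2 difference was -3.24 with a standard error of 0.20 (limma, adjusted p = 4.72e-06), and an exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 samples allow. The labels therefore match the targeted gene in all 8 libraries. Of the 50-base windows along Acot2 exons, 24.5% also occur in its neighbour Acot1, so the counts of this pair are uncertain to the extent that shared reads were counted.

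**Figure D1:**
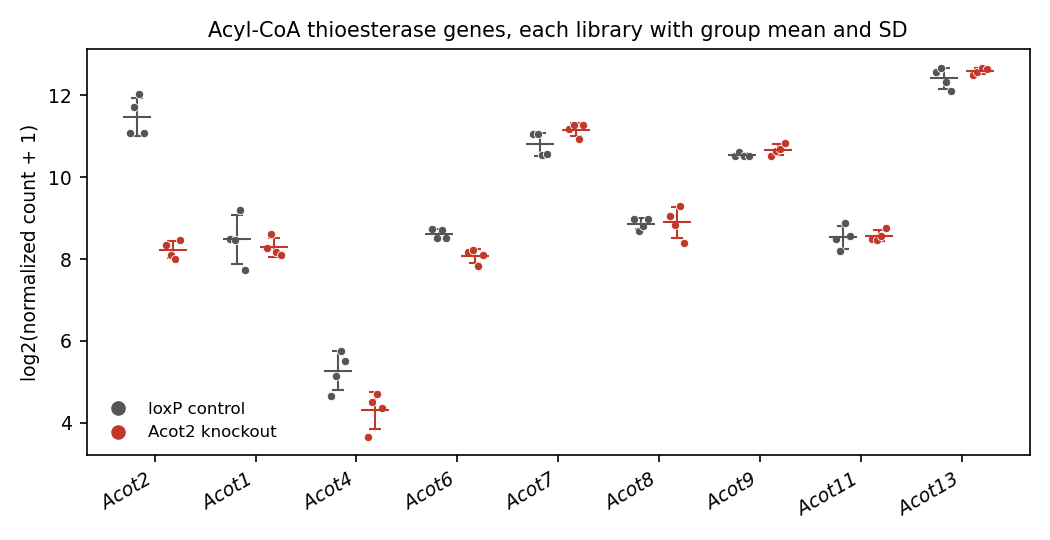
Normalized counts of 9 acyl-CoA thioesterase genes as log2(normalized count + 1) on the vertical axis, with a point for each library, a horizontal bar for the group mean and a vertical bar for the SD (n = 4 per group). Acot2 separates the groups by -3.24 log2 units, while Acot1 differs by -0.19.

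The other thioesterases did not pass over all genes. Adjusted over the list alone, 2 members were lower, Acot2 and Acot6 (adjusted p = 0.0165 for Acot6), and 0 were higher, against 1 at an unadjusted p under 0.05 by limma. Acot1, a cytosolic enzyme, had a log2 difference of -0.19 ± 0.25 (SE, limma, adjusted p = 0.643; exact two-sided permutation p = 0.629). The values were -0.54 for Acot6 (adjusted p = 0.0796), -0.96 for the low-count gene Acot4 (adjusted p = 0.148) and 0.36 for Acot7 (adjusted p = 0.138). Acot13, Acot9, Acot11 and Acot8 differed by 0.17, 0.13, 0.04 and 0.03, and the sign of Acot13, Acot11 and Acot8 turned under some alternatives. Acot3, Acot5, Acot10 and Acot12 were too low to test. Among the 10 tested members of the thioesterase list, the median difference was 0.03 and the mean -0.41, and the list did not pass (camera, adjusted p = 0.503).

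Genes beside Acot2 on chromosome 12 fell as a list. Of 16 tested members 11 had lower and 5 higher estimates, with a median of -0.28 (camera, adjusted p = 0.0469; adjusted p = 0.936 with an estimated correlation). No member passed over all genes. Adjusted over the list alone, 4 were lower and 1 was higher. Papln had a log2 difference of -1.62 ± 0.37 (SE), and Numb, a regulator of Notch signalling, of -0.37 ± 0.12. Without the Acot genes the median stayed near, at -0.25, but the list no longer passed (camera, adjusted p = 0.223). Nor did it pass without control replicate 1, 2 or 3 or knockout replicate 5, 7 or 8, each left out alone (medians -0.33 to -0.20, adjusted p = 0.0518 to 0.137). It passed under 8 of 25 alternatives, and was also lost with other filters, equal totals, quantile normalization, voom, the trend removed and without control replicates 3 and 4 (medians -0.27 to -0.14 apart from voom at -0.28, adjusted p = 0.0525 to 0.125). With the trend removed and control replicates 3 and 4 left out together, the median shrank to -0.09 (camera, adjusted p = 0.155). By fry the adjusted p was 0.208.

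The lists for fuel use did not pass. In the mitochondrial β-oxidation list, 13 of 22 members had higher and 9 lower estimates, with a median of 0.05 (camera, adjusted p = 0.949). Adjusted over the list alone, 1 member was higher and 1 lower, and none passed over all genes. Etfb, a subunit of the electron transfer flavoprotein, differed by 1.03 ± 0.24 (SE), and Cpt1b, the muscle carnitine palmitoyltransferase, by -1.42 ± 0.40. Both counts are uncertain, because 81.4% of the exon bases of Cpt1b and 58.2% of those of Etfb lie in exons of another annotated gene on the same strand. The Cpt1b count was only 68.8 in controls and 27.1 in knockouts. For targets of the lipid-sensing PPAR receptors, 16 of 28 members were lower, with a median of -0.06 (adjusted p = 0.659). For peroxisomal β-oxidation, the median was 0.03 (adjusted p = 0.969), with Acaa1a, a thiolase, at 0.53 ± 0.13 (SE). The fatty acid uptake and activation list had a median of 0.01 (adjusted p = 0.977), with Fabp4, a fatty acid binding protein of adipocytes, at 0.75 ± 0.21 and Acsl1, an acyl-CoA synthetase, at -0.56 ± 0.15. Triglyceride and lipid droplet genes had a median of 0.14 (adjusted p = 0.737). Within that list Hilpda, an inhibitor of the lipase Pnpla2, differed by 0.71 ± 0.18, and Abhd5, its activator, by -0.53 ± 0.14. Neither passed over all genes (limma, adjusted p = 0.0796 each), and Pnpla2 itself differed by 0.09. Hilpda was lowest and Abhd5 highest in control replicates 3 and 4. Across the alternatives Hilpda ran from 0.37 to 0.82 and Abhd5 from -0.66 to -0.27. Lipogenesis and desaturation had a median of -0.04 (adjusted p = 0.737). The glycolysis and glycogen list had a median of -0.05 (adjusted p = 0.877), and the pyruvate dehydrogenase and TCA cycle list one of -0.04 with a mean of 0.01 (adjusted p = 0.949).

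Ribosomal and respiratory chain genes rose as lists. Of 75 cytosolic ribosomal protein genes, 73 had higher estimates, with a median of 0.40 (camera, adjusted p = 6.05e-11; adjusted p = 0.936 with an estimated correlation). Of 76 mitochondrial ribosomal protein genes, 72 were higher, with a median of 0.34 (adjusted p = 6.19e-11; adjusted p = 0.936 with an estimated correlation). Nuclear genes of complex I were higher in 35 of 36, with a median of 0.47 (adjusted p = 2.88e-09; adjusted p = 0.936 with an estimated correlation). Those of complexes III to V were higher in 33 of 36, with a median of 0.52 (adjusted p = 9.14e-08; adjusted p = 0.936 with an estimated correlation). No member passed over all genes. Adjusted over the list alone, 34, 32, 26 and 26 members were higher and 0 lower in these lists in turn. Ndufa5 of complex I differed by 0.71 ± 0.18 (SE), Atp5o of ATP synthase by 0.66 ± 0.16, Rps9 by 0.69 ± 0.19 and Mrps30 by 0.50 ± 0.12.

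These lists had low scores in control replicates 3 and 4. The mean deviation of the cytosolic ribosome list was -0.45 and -0.53 in these libraries, 0.17 and 0.07 in control replicates 1 and 2, and between 0.16 and 0.22 in the knockouts. The libraries also differed by transcript length. Genes in the quartile of shortest transcripts had a median deviation of -0.29 and -0.33 in control replicates 3 and 4 and of 0.09 to 0.16 in the knockouts. Across 11495 genes, which are not independent replicates, Spearman's rho between exon length and the knockout difference was -0.52. The next alternatives were chosen after seeing the data. With this trend removed all 4 lists passed (medians 0.18 to 0.25, adjusted p = 4.1e-05 to 0.000261), and so they did without control replicates 3 and 4 (medians 0.07 to 0.18, adjusted p = 0.000161 to 0.0111). With both at once the mitochondrial ribosome list passed (median 0.11, adjusted p = 0.0198) and the cytosolic ribosome, complex I and complexes III to V lists did not (medians 0.02 to 0.12, adjusted p = 0.0769 to 0.895).

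**Figure D2:**
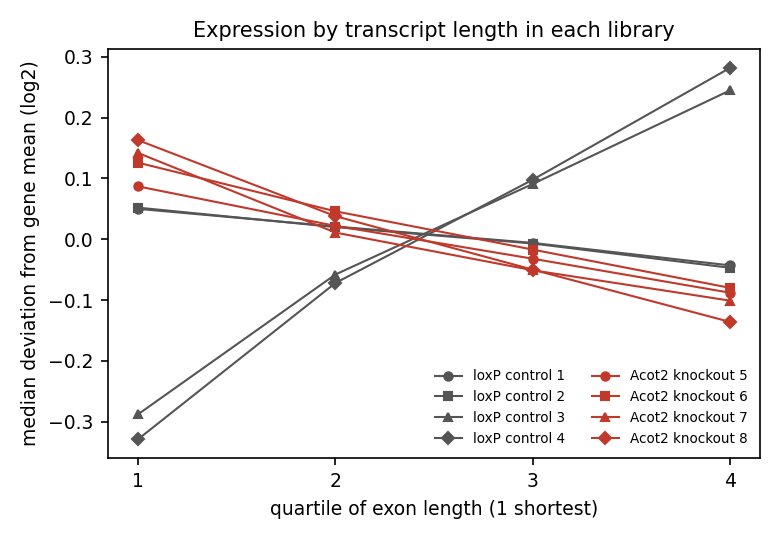
Median deviation from each gene's mean over the 8 libraries, in log2 units, for genes grouped into quartiles of exon length, with a line for each library. Control replicates 3 and 4 run from -0.29 and -0.33 in the shortest quartile to 0.25 and 0.28 in the longest, opposite to the other 6 libraries.

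The mRNAs encoded by mitochondrial DNA fell as a list. All 13 had lower estimates, with a median of -1.01 (camera, adjusted p = 0.000275; adjusted p = 0.936 with an estimated correlation). No member passed over all genes, and 3 were lower adjusted over the list alone. The cytochrome c oxidase subunit mt-Co1 differed by -1.01 ± 0.29 (SE), and the complex I subunit mt-Nd5 by -1.35 ± 0.39. These mRNAs took 7.25%, 6.15%, 10.5% and 9.44% of the counts in control replicates 1 to 4, and 7.09%, 3.09%, 5.93% and 2.3% in knockout replicates 5 to 8. Without knockout replicate 6 the median was -0.89 (adjusted p = 0.00403) and without knockout replicate 8 it was -0.77 (adjusted p = 0.00404). Without both, an alternative added after seeing the data and picked for their low shares, the median was -0.20 and the list did not pass (adjusted p = 0.513).

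**Figure D3:**
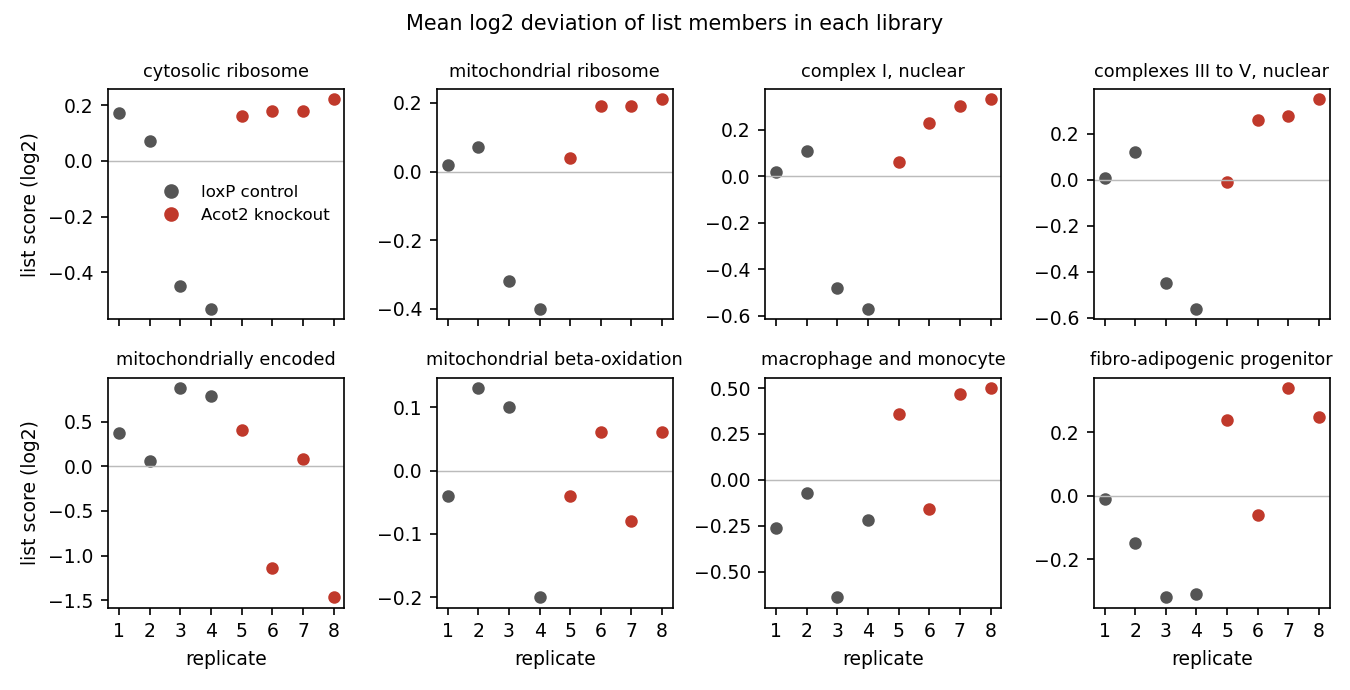
Mean log2 deviation of the tested members of 8 gene lists in each library, with replicate number on the horizontal axis and a point for each library. The mitochondrially encoded list lies at -1.14 and -1.47 in knockout replicates 6 and 8 and at 0.41 and 0.08 in replicates 5 and 7.

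Macrophage and connective tissue genes rose as lists. All 13 macrophage and monocyte markers had higher estimates, with a median of 0.50 (camera, adjusted p = 0.000259; adjusted p = 0.936 with an estimated correlation). Adjusted over the list alone, 9 were higher and none passed over all genes. The complement genes C1qa and C1qc differed by 1.10 ± 0.22 (SE) and 0.78 ± 0.22, and the lysozyme gene Lyz2 by 0.64 ± 0.17. Markers of fibro-adipogenic progenitors, the connective tissue stem cells of muscle, were higher in 11 of 11, with a median of 0.35 (adjusted p = 0.000559; adjusted p = 0.936 with an estimated correlation). Adjusted over the list alone, 8 of these were higher. Clec3b differed by 0.81 ± 0.16 and Gsn by 0.44 ± 0.13. The extracellular matrix list was higher in 18 of 22, with a median of 0.28 (adjusted p = 0.00842; adjusted p = 0.957 with an estimated correlation), and 0 members passed adjusted over the list alone, against 10 at an unadjusted p under 0.05 by limma. Among its members, Ctgf differed by 0.65 ± 0.18 and Sparc by 0.59 ± 0.19. Knockout replicate 6 lay within the control range for macrophage markers (score -0.16, controls -0.64 to -0.07) and for fibro-adipogenic markers (-0.06, controls -0.32 to -0.01), above 3 of the 4 controls in each. Its extracellular matrix score of -0.31 was the lowest of the 8 libraries. The matrix call was lost without control replicate 1 or 2 or knockout replicate 8 (medians 0.20 to 0.26, adjusted p = 0.0634 to 0.0886).

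**Figure D4:**
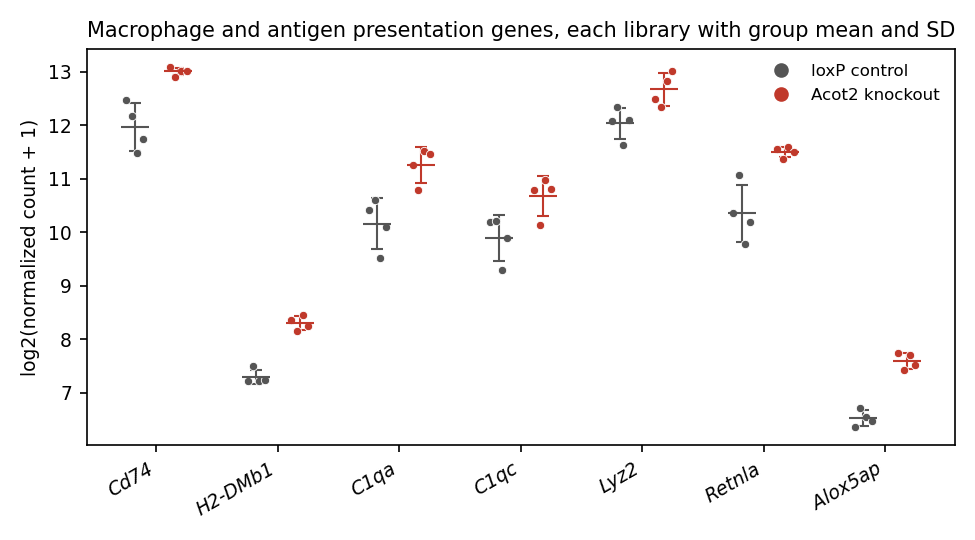
Log2(normalized count + 1) of 7 macrophage, antigen presentation and related immune genes, with a point for each library, a horizontal bar for the group mean and a vertical bar for the SD (n = 4 per group). The 4 knockout values of Cd74 and of H2-DMb1 lie above all 4 control values, and neither gene passed the test over all genes.

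The endoplasmic reticulum stress and immediate early lists rose by smaller amounts. The first was higher in 14 of 18, with a median of 0.16 (camera, adjusted p = 0.0364; adjusted p = 0.936 with an estimated correlation), with the chaperones Pdia3 at 0.42 ± 0.11 (SE) and Hsp90b1 at 0.40 ± 0.12. The second was higher in 17 of 22, with a median of 0.26 (adjusted p = 0.0468; adjusted p = 0.936 with an estimated correlation), with Ier5 at 0.64 ± 0.16 and Ier2 at 0.76 ± 0.21. The stress call was lost without control replicate 2 or 3 or knockout replicate 7 or 8 (medians 0.14 to 0.17, adjusted p = 0.0514 to 0.101), and the immediate early call without control replicate 1 or 2 or knockout replicate 7 (medians 0.16 to 0.27, adjusted p = 0.0552 to 0.195). With the length and GC trend removed the immediate early median was 0.13 (adjusted p = 0.383), and without control replicates 3 and 4 the stress median was 0.09 (adjusted p = 0.23).

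The remaining lists did not pass as reported. The interferon-stimulated list had a median of 0.26 (camera, adjusted p = 0.0981). It passed under 5 of 25 alternatives, which were no filter, voom, and without control replicate 2 (median 0.40, adjusted p = 0.000395), knockout replicate 6 (0.28, adjusted p = 0.0245) or knockout replicate 7 (0.39, adjusted p = 0.0308), and its median was -0.06 without control replicates 3 and 4. Of the other lists, the circadian clock list had a median of -0.19 (adjusted p = 0.109), inflammatory mediators 0.28 (adjusted p = 0.175), heat shock 0.18 (adjusted p = 0.193) and the integrated stress response 0.10 (adjusted p = 0.228). Fibre type lists had medians of 0.14 for fast glycolytic (adjusted p = 0.506) and 0.26 for slow and oxidative genes (adjusted p = 0.399). The slow and oxidative median depended on single libraries: it was 0.50 without control replicate 3, where the list passed (adjusted p = 0.00656), 0.01 without control replicate 4, 0.46 and 0.41 without knockout replicates 5 and 7, and 0.16 without knockout replicate 8. The calcium buffer Pvalb of fast fibres differed by 0.81 ± 0.21 (SE). Knockout replicate 8 also held heart transcripts, such as Myl7 at 1124.4 against at most 4.1 in the other 7 libraries, a gene chosen after its values were seen. Among other cell types, white adipocyte (median 0.25), tendon (0.22), erythroid (0.24), B and plasma cell (0.24), T and NK cell (0.13), smooth muscle and pericyte (0.12), endothelial (0.01), satellite cell (0.01) and Schwann cell markers (-0.06) did not pass, and too few neutrophil markers were measured for a test. Under 1 alternative each, inflammatory mediators passed with no filter (median 0.28, adjusted p = 0.0282), heat shock without control replicates 3 and 4 (0.15, adjusted p = 0.0427) and white adipocyte markers without knockout replicate 7 (0.51, adjusted p = 0.0303). Without knockout replicates 6 and 8, tendon (0.65, adjusted p = 0.000288) and integrated stress response genes (0.23, adjusted p = 0.0435) passed. The antioxidant, mitochondrial proteostasis, mitochondrial biogenesis, branched-chain amino acid, muscle atrophy, sterol synthesis, denervation and glucocorticoid lists had medians of 0.07, 0.03, -0.06, -0.05, -0.07, -0.01, -0.03 and -0.09 (adjusted p = 0.432 to 0.977). Median and mean, or median and test, had opposite signs in the thioesterase, sterol synthesis, TCA cycle, denervation, Schwann cell and glucocorticoid lists.

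At the level of single genes, limma called 0 genes higher and 1 lower. At an unadjusted p under 0.05, 2135 genes were higher and 2080 lower, 26.9% of those tested, where chance alone gives 783 on average. The 4 and 4 values did not overlap in 2055 genes, 13.1% of those tested, against 2.9% by chance on average. Neither average gives the spread, which is wide where genes vary together. Other splits of the 8 libraries into 4 and 4 gave 127 to 3340 genes at an unadjusted p under 0.05. The next smallest adjusted p was 0.0587, for Sav1, a scaffold protein of the Hippo pathway, with a log2 difference of -1.09 ± 0.16 (SE) and no overlap between the groups. The lower genes of next smallest p were Ankrd23 (-0.66 ± 0.11), Uevld (-0.78 ± 0.14) and Zfp109 (-2.51 ± 0.46). The higher genes of smallest p were H2-DMb1 (1.02 ± 0.17) and Cd74 (1.04 ± 0.18), which serve antigen presentation, Dpysl2 (1.20 ± 0.22), Retnla (1.15 ± 0.21) and Alox5ap (1.08 ± 0.20), which serves leukotriene synthesis. The 8 genes after Sav1 each had an adjusted p of 0.0796 and did not pass. Without control replicates 3 and 4, a fit chosen after seeing the data, Cd74 differed by 0.68 and H2-DMb1 by 0.95. Sav1 differed by -0.79 and Ankrd23 by -0.55 in that fit (limma, adjusted p = 0.12 to 0.469 for these genes). Exon bases of Ankrd23 lie in exons of another same-strand gene for 78.2% of its length. Without control replicate 1 the test called 1722 genes, and without control replicate 2 it called 2048. The 4215 genes at an unadjusted p under 0.05 became 2529 without control replicate 3, 2744 without control replicate 4 and 1250 without both, where 1 gene was called in each case. They became 2947 without knockout replicate 8, 3300 without knockout replicate 7, 3593 without knockout replicate 6, 4135 without knockout replicate 5 and 1994 without knockout replicates 6 and 8, but 4941 without control replicate 1 and 4961 without control replicate 2.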

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

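The fits with the trend removed and those without 2 libraries were chosen after seeing the data, as were the tests of blood and of mitochondrial rRNA. Only the splits of the samples, the fits without 1 library and the search for outlying values were set before. Some genes in that search were added after their values were seen.

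A value far from the other 3 of its group was found in 17 of 300 groups of 4 values, where chance gives about 15. The groups include genes added after their values were seen, so these counts cannot be compared fairly. For genes, the outlying log2 normalized counts were 7.49 for H2-DMb1, 10.79 for Myh11 and 11.19 for Hba-a2 in control replicate 2, 16.68 for Gsn in control replicate 1, 10.67 for Ctgf and 11.77 for Col5a1 in control replicate 4, 12.47 for Bhlhe41 in knockout replicate 5, and 11.81 for Cldn5 in knockout replicate 8. Genes added after their values were seen gave 10.69 for Nppa, 10.14 for Myl7 and 11.55 for Myl4 in knockout replicate 8, and 11.11 for Kbtbd12 in knockout replicate 6, against 13.05 to 13.17 in the other 3 knockouts. Outlying list scores were -0.26 for the thioesterases and 0.04 for the mitochondrial ribosome in knockout replicate 5, -0.08 for sterol synthesis in control replicate 2, -0.15 for endothelial markers in control replicate 4, and 0.14 for smooth muscle and pericyte markers in knockout replicate 8.

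Of the 35 splits of the 8 libraries into 4 and 4, only the real one, 1 of 35, called a gene, and the highest of the others called 0. That gene is Acot2, deleted by design, so this count says nothing of the other genes. At an unadjusted p under 0.05 the real split gave 4215 genes and the highest other 3340, so 1 of 35 was as large. This count follows control replicates 3 and 4: the 14 other splits that keep them together gave 524 to 3340 genes, the 20 that part them 127 to 584, and without both libraries the real count was 1250. Knockout libraries moved it too, to 2947 without replicate 8 and 1994 without replicates 6 and 8. The real split ranked first, which argues against chance for the count as a whole. Since 1 of 35 is the smallest share these splits can give, chance is not excluded, nor is a structure of the samples that these libraries bring. Chance cannot be excluded for the number of lists: 8 of 35 splits called at least as many as the real 11, and the highest other called 14.

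Ribosomal and respiratory chain genes rose together with a median over the 4 lists of 0.38. The SE beside this and the following medians is that of the members' mean score between libraries, not of the median itself. Removing the length and GC trend left 51% of it (0.20, SE 0.09), which leaves the part of that trend open. Leaving out control replicates 3 and 4 left 33% (0.13, SE 0.06), and both together left 17% (0.07, SE 0.04), but these 2 libraries had the lowest scores for these lists, so both falls decide nothing. The length and GC trend and an effect of the knockout on these genes stay open.

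Macrophage and monocyte genes rose with a median of 0.50. Removing the length and GC trend left 101% (0.50, SE 0.19), which argues against that trend as the main source. The error is too large to exclude a part of it. Without control replicates 3 and 4 the median kept 96% (0.48, SE 0.24), but with 2 controls left its error is too large to exclude their part. The macrophage score rose by 0.35 (SE 0.24) more than the mean of the T cell, B cell and erythroid scores, which does not exceed its error enough to exclude more blood or lymphoid tissue in the knockout pieces. An effect of the knockout stays open as well, untested against differences in how the tissue was cut.

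Mitochondrially encoded mRNAs fell with a median of -1.01. Without knockout replicates 6 and 8 the difference kept 20% (-0.20, SE 0.30), but these libraries were picked for their low share of these mRNAs, so that fall decides nothing. Without replicate 6 alone the median was -0.89 and without replicate 8 alone -0.77, and the list passed in both. Without control replicates 3 and 4 it kept 74% (-0.74, SE 0.69), which decides nothing. The mitochondrial rRNAs differed by 0.08 on the log2 scale, which argues against less mitochondrial RNA of every kind, with the limit that how rRNA was removed from the libraries is not given. An effect of the knockout stays open.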

How the results depend on the processing

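The edgeR and DESeq2 alternatives set in advance were not run, since the deposited unit is log2. Voom, the trend removal and the fits without 2 libraries were chosen after seeing the data. No paired analysis was possible because the groups share no replicate numbers. Acot2 kept its direction and passed under all 22 gene-level alternatives, from -3.44 to -3.06 (adjusted p 6.93e-08 to 0.0109). The count of 1 gene became 2 lower genes with no filter and with equal totals (Sav1 joined), 7 (4 higher, 3 lower) without trend and robust options, and 1201 (593 higher, 608 lower) with quality weights. It became 5 (1 higher, 4 lower) with the trend removed, and 2 (1 higher) without knockout replicates 6 and 8, where Kbtbd12 joined. Voom called 1. With 1 replicate left out in turn it ran from 1 to 2048, higher genes from 0 to 1024 and lower genes from 1 to 1024, with 1722 without control replicate 1 and 2048 without control replicate 2. The 0 higher genes stand beside 2135 at an unadjusted p under 0.05. Sav1 passed under 6 of 22 alternatives (adjusted p 0.00491 to 0.385). The 11 lists became 5 with the trend removed and without control replicates 3 and 4 (macrophage, fibro-adipogenic, extracellular matrix, mitochondrially encoded and mitochondrial ribosome), and 0 with an estimated correlation (smallest adjusted p 0.936) and 0 with fry (smallest adjusted p 0.208 among these lists), beside the 11 by camera, and 8 to 12 with 1 replicate left out. The cause of these moves was not tested beyond the tests given for the patterns above. In simulations at these depths, with genes drawn independently, a 1.5-fold change was called in only 26.9% of genes. Of the lists that had not passed, interferon-stimulated genes passed under 5 alternatives and slow and oxidative fibre, white adipocyte, tendon, heat shock, inflammatory mediators and the integrated stress response under 1 each. No list that passed as reported changed the sign of its median. Medians of 28 lists that had not passed and differences of 5 named genes that had not passed changed sign under some alternative. They moved with no filter to -0.02 (acyl-CoA thioesterases), 0.06 (denervation and regeneration). They moved with equal totals to 0 (sterol synthesis). They moved with quantile normalization to 0 (fatty acid uptake and activation). They moved with quality weights to -0.02 (fatty acid uptake and activation), 0.01 (denervation and regeneration), -0.01 (endothelial, satellite cell). They moved with the trend removed to -0.17 (Acot13, erythroid), -0.25 (Acot8), -0.20 (acyl-CoA thioesterases), -0.01 (peroxisomal beta-oxidation, mitochondrial proteostasis), -0.02 (triglyceride and lipid droplet), 0.04 (lipogenesis and desaturation, denervation and regeneration), 0.02 (branched-chain amino acid catabolism, glucocorticoid response), -0.03 (integrated stress response), -0.06 (antioxidant and NRF2 targets, fast glycolytic fibre), -0.05 (B and plasma cell). They moved without control replicates 3 and 4 to -0.03 (Acot13, white adipocyte), -0.02 (mitochondrial beta-oxidation, triglyceride and lipid droplet), -0.04 (peroxisomal beta-oxidation), 0.03 (sterol synthesis), 0 (antioxidant and NRF2 targets), 0.04 (denervation and regeneration), -0.06 (interferon-stimulated). They moved without knockout replicates 6 and 8 to -0.42 (Jchain), -0.01 (peroxisomal beta-oxidation), 0 (lipogenesis and desaturation), 0.03 (glycolysis and glycogen), -0.05 (mitochondrial proteostasis), 0.11 (glucocorticoid response), -0.16 (slow and oxidative fibre). They moved with the trend removed and without control replicates 3 and 4 to -0.15 (Acot13), -0.02 (Acot8), -0.09 (acyl-CoA thioesterases), -0.01 (mitochondrial beta-oxidation, peroxisomal beta-oxidation, T and NK cell), -0.04 (triglyceride and lipid droplet), 0.06 (sterol synthesis), -0.03 (integrated stress response, fast glycolytic fibre), 0.03 (denervation and regeneration), -0.05 (interferon-stimulated, erythroid), -0.10 (white adipocyte). With 1 replicate left out in turn, the ranges that crossed 0 were fatty acid uptake and activation 0 to 0.08, denervation and regeneration -0.04 to 0.13, satellite cell -0.03 to 0.08, Acot11 -0.08 to 0.16, Acot8 -0.10 to 0.19, acyl-CoA thioesterases -0.05 to 0.06, lipogenesis and desaturation -0.19 to 0.01, sterol synthesis -0.05 to 0.02, pyruvate dehydrogenase and TCA cycle -0.09 to 0.03, endothelial -0.04 to 0.08, Schwann cell -0.17 to 0.05, Acot1 -0.44 to 0.05, PPAR targets -0.12 to 0.03, mitochondrial biogenesis and dynamics -0.09 to 0.01, T and NK cell -0.03 to 0.32, mitochondrial beta-oxidation -0.03 to 0.11, peroxisomal beta-oxidation -0.02 to 0.08, smooth muscle and pericyte -0.02 to 0.24, white adipocyte -0.11 to 0.51, glycolysis and glycogen -0.06 to 0.04, mitochondrial proteostasis -0.02 to 0.06, glucocorticoid response -0.14 to 0.03.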

Other observations

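The genes in this part were chosen after their values were seen, as were the test of a mislabelled sample and that of chromosome 12. The heart genes that decide the first hypothesis were listed before their values were seen.

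For 4 genes picked after their values were seen, all from the MHC class II region, the 4 knockout counts lay above the 4 control counts, a separation of the groups that 13.1% of all tested genes show in either direction. No list of such genes was tested. H2-Aa was 1842 ± 480 in controls and 3075 ± 471 in knockouts (SD, n = 4 each), H2-Ab1 1920 ± 615 and 3597 ± 405, H2-Eb1 1846 ± 526 and 3466 ± 385, and H2-DMa 255.2 ± 75.5 and 407.6 ± 29.1. In all 4 genes the lowest control counts were those of control replicates 3 and 4, which lowers the control means. For H2-Ab1 these were 1278.8 and 1597.3, against 2679.3 and 2125 in control replicates 1 and 2. The platelet factor gene Pf4, also made by macrophages, was 492.9 ± 156 and 1129 ± 265. Spag6l was 24.9 ± 1.71 in controls and 11.2 ± 0.434 in knockouts. Kbtbd12 was 9186.8, 8477 and 8639.5 in knockout replicates 5, 7 and 8 but 2213.2 in replicate 6, where the controls lay between 2280.7 and 3432.8. The brown fat gene Ucp1 was 1458.2 and 885.1 in knockout replicates 5 and 8, 133.4 in control replicate 3 and at most 16.8 in the other libraries, and Cidea was 927.9 and 858.2 in those knockouts and at most 252.8 elsewhere.

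Knockout replicate 8 alone held transcripts of atrial heart muscle: Nppa, the atrial natriuretic peptide, at 1648.1 and Myl7, the atrial myosin light chain, at 1124.4, against at most 6.1 and 4.1 in the other 7 libraries. A hypothesis is that this piece held RNA from heart muscle. It was tested on 16 heart genes. Their median excess in replicate 8 over the other 7 libraries was 2.61 log2 units, and in no other library did the same median exceed -0.01. Of the 16, 10 exceeded 2 log2 units, among them Myh6 (2522.1 against at most 522.1), Tnnt2 (2252.4 against at most 417.7) and Kcnj5 (52.5 against at most 0.7). The others did not. Of these, Dkk3, Sbk2, Gja5 and Tbx5 are also expressed in the other libraries. Bmp10 and Hamp, at 1.2 and 0 in replicate 8, lay below the floor for detection there. A mislabelled control is argued against, since Acot2 in replicate 8 lay 2.61 log2 units below the lowest control, with a control SD of 0.47. Heart muscle RNA in this library may thus be the source, by contact in dissection or between libraries, which these values cannot separate.

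Near Acot2 on chromosome 12, within 10 Mb, 26 of 136 tested genes (19.1%) had no overlap between groups, against 13.1% elsewhere, and 17 of the 26 were lower in the knockout. Fisher's exact test gave p = 0.0544 over genes, which are not independent, so a higher share is not shown. A segment of the chromosome that travels with the targeted allele would be in both groups, since the controls carry loxP sites at both copies of Acot2 and a knockout by Cre needs them too. The design thus gives no reason for such a segment to differ, though its extent in each group was not tested. Sav1, the gene of next smallest adjusted p after Acot2, starts at 69965012 on this chromosome. It lies outside the 10 Mb window, which was chosen after seeing the data.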
